A study of Mus musculus with 6 samples.

How the data were processed

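Total RNA of cultured mouse fibroblast-like synoviocytes was measured on 6 Affymetrix whole-transcript arrays, 3 of cells infected with an empty adenovirus (Mock) and 3 of cells infected with an adenovirus carrying Epas1 (Ad-Epas1). Per the labels, the cells came from knee synovium digested with collagenase for 4 h and were used between passages 4 and 8, and 300 ng of total RNA entered the labelling of each array. The labels call the replicates biological but do not say whether they came from separate animals or cultures, so the p-values measure the spread between these samples, part of which may be technical. Arrays have no read depth, and their number (3 against 3) limits the precision. An exact permutation test of 3 against 3 could not go below p = 0.1, so the tests rest on a model that shares the spread across genes.

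The values are log2 expression values, 1 per probe set and array, which the authors deposited after RMA (background correction, quantile normalization and probe summary) in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. Quantile normalization gives the arrays nearly one distribution, so a change shared by most genes cannot be seen, and probe summaries compress large fold changes. The genome build behind the probe sets is not given in the sources used here, and no coordinates are printed. No column of another sample was present (0 columns).

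Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and were not named, and 16010 had no gene and were not used in the gene tests. The Entrez identifiers of 23328 of the 23521 were in a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols, and the others kept the annotation's symbol. A gene with several probe sets (1082 genes) was represented by the probe set with the highest mean over the 6 arrays, which left 22180 genes. No filter on level was applied. As a reference for genes not expected in these cells, 1394 olfactory and vomeronasal receptor genes had a median level of 4.34 and a 95th percentile of 6.62.

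Ad-Epas1 was compared with Mock by limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 22180 genes and a threshold of 0.05. Counts are also given with a change of at least 1.5-fold. Values for groups are means ± SD over 3 arrays, and SE is the moderated standard error of the log2 fold change. Samples were grouped by their titles. The 26 gene lists were fixed before the data were examined. They cover the HIF pathway, glycolysis, other hypoxia-responsive genes, matrix proteases, collagens and matrix structure, inflammatory mediators, NF-kB, bone regulation, interferon-stimulated genes, cell cycle, p53 and apoptosis, stress responses, cholesterol and fatty acid synthesis, oxidative phosphorylation, iron and antioxidant genes, immediate-early genes, TGF-beta targets, 8 kinds of cell markers and sex-linked genes. They hold 558 symbols, of which 519 were measured and 39 were not analysed here. For 3 symbols the current name was used. The list of 4 measured sex-linked genes was only described, and the other 25 lists were tested by limma's camera with its preset inter-gene correlation of 0.01, two-sided, adjusted over the 25 lists. Lists overlap in some members, and several fibroblast genes occur in both matrix and fibroblast marker lists. A member count adjusted over the list alone repeats the Benjamini-Hochberg step over that list's members.

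The genes named in the text were chosen by a rule written before the data were examined: all measured HIF pathway components; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, leaving out predicted or unnamed symbols (1 in each direction); up to 3 members of each list with the smallest p; and Mmp3, Mmp9, Mmp13, Adamts4, Il6, Cxcl1, Ptgs2, Nampt, Tnfsf11 and Tnfrsf11b whatever their p. This gave 109 genes. Of these, 7 had more than 1 probe set, and for 0 of the called ones did the probe sets differ in sign. The dimmer probe sets of Sfrp2 (log2 fold change -0.04, adjusted p = 0.86), Slc7a11 (1.63, 0.15) and Slc2a1 (0.48, 0.096) did not pass. These values come from limma over all probe sets with 1 gene symbol. Genes named outside the rule are marked as such.

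Alternatives listed before the data were examined were a replicate block, leaving out each array in turn, another quantile step between arrays, centring each array on its median, only genes above the median level, a variance prior with trend and robust fitting, array weights, the mean over a gene's probe sets, every probe set tested separately, and a per-gene test without shared variance. For the lists, camera with an estimated correlation and fry were run. After seeing the data, a fit without both Mock replicate 1 and Ad-Epas1 replicate 3, each list's member count without Ad-Epas1 replicate 3, the count of changed probe sets without a gene with each array left out, and the lists without Epas1, the gene the virus delivers, were added. The fits were tested on simulated data for this comparison, with the 22180 genes, the residual spread of the real arrays, genes drawn independently of each other and 50 genes changed at each fold. At 1.5-fold 48% of changed genes were called, at 2-fold 88%, at 4-fold 100% and at 8-fold 98%, and 8 of 21955 unchanged genes were called. There, 5 of 200 random lists had a camera p under 0.05. With genes drawn independently, this does not show how camera behaves on lists whose members vary together. The cell cycle list, for example, had an estimated correlation of 0.65. With no change simulated, limma called 0 genes. Figures were drawn with matplotlib 3.10.9.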

Results

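Gene expression was measured in cultured fibroblast-like synoviocytes, the connective tissue cells of the joint lining, grown from knee synovium of C57BL6 mice. The cells were between passages 4 and 8. They were exposed for 2 h to an adenovirus at a multiplicity of infection of 800 and cultured for 24 h. On 3 arrays the cells had received a virus without an insert (Mock), and on 3 a virus carrying Epas1 (Ad-Epas1). Epas1 encodes HIF-2alpha, an oxygen-regulated transcription factor. The comparison asks which transcripts change in these cells when Epas1 is delivered by a virus. Each array gave values for 41345 probe sets, from which 22180 genes were tested, and the array medians lay between 6.77 and 6.84 on the log2 scale. The number of arrays limits the precision of every value below.

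Epas1 rose 22.6-fold, from 8.63 ± 0.11 in Mock to 13.13 ± 0.02 in Ad-Epas1 (log2 mean ± SD, n = 3 each, probe set 17340197). This was a log2 fold change of 4.50 with an SE of 0.08 (limma, adjusted p = 4.6e-06), and all 3 Ad-Epas1 arrays lay above all 3 Mock arrays. Hypoxia-responsive and inflammatory genes were among those that rose, and genes of cell division and of bone regulation among those that fell. In total, 1458 genes rose and 2162 fell at an adjusted p under 0.05 (3620 genes). With a change of at least 1.5-fold, 569 rose and 1151 fell (1720 genes). The balance of rises and falls varied with the scaling. With each array centred on its median 1732 genes rose and 1928 fell, and 626 and 1061 at 1.5-fold or more. The groups did not overlap for any of the 3620 genes. They did not overlap for 39.7% of all genes, where chance gives 10%. The counts varied with the arrays entered: 2186 genes passed without Ad-Epas1 replicate 1, 1512 without Ad-Epas1 replicate 2, 1187 without Mock replicate 2 and 1181 without Mock replicate 3, against 5390 without Ad-Epas1 replicate 3, on which the macrophage markers had a median of -3.80 from the Mock mean. For changes of at least 1.5-fold the count was 1092 without Ad-Epas1 replicate 2, 954 without Mock replicate 2 and 962 without Mock replicate 3, and it was 2457 without Ad-Epas1 replicate 3.

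**Figure D1:**
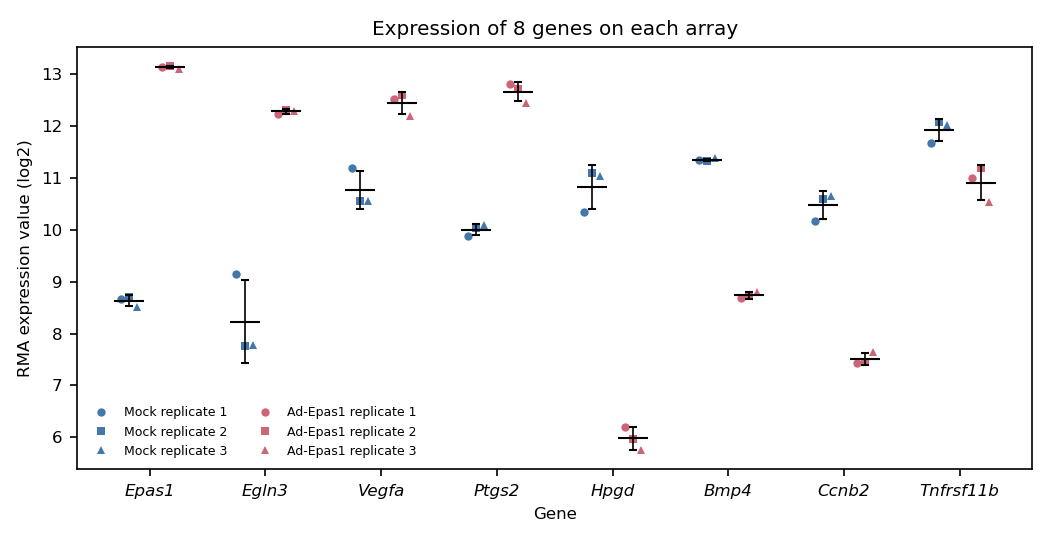
RMA expression values (log2, vertical axis) of 8 genes (horizontal axis) on each of the 6 arrays, with blue for Mock, red for Ad-Epas1, symbols for the replicate numbers, and black bars for the group mean and SD (n = 3). Epas1 moved from a mean of 8.63 to 13.13 and Hpgd from 10.8 to 5.98, and for each of the 8 genes the groups did not overlap.

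Of the 11 measured components of the HIF pathway, 3 rose, 2 fell and 6 did not pass the test (4 rose and 2 fell adjusted over the list alone). Besides Epas1, the risen members were Egln3, a prolyl hydroxylase that marks HIF-alpha proteins for degradation (log2 fold change 4.05, SE 0.36, adjusted p = 0.0018), and Vhl, which encodes the ubiquitin ligase subunit that recognises them (0.75, SE 0.12, adjusted p = 0.010). Arnt2, a dimerisation partner of HIF-alpha proteins, fell by 1.41 (SE 0.11, adjusted p = 9.9e-04), and Cited2, which restrains HIF-driven transcription, fell by 0.45 (SE 0.09, adjusted p = 0.018). Hif1a differed by 0.06 with a 95% interval from -0.11 to 0.23 (adjusted p = 0.58). The differences of Arnt (0.08, adjusted p = 0.46), Hif3a (0.15, adjusted p = 0.24), Egln1 (0.28, adjusted p = 0.14), Egln2 (0.12, adjusted p = 0.31) and Hif1an (0.21, adjusted p = 0.10) did not pass either. Cited2 lost its call without Mock replicate 2, Mock replicate 3 or Ad-Epas1 replicate 2 (adjusted p up to 0.083), and Vhl without Mock replicate 2 or 3 (up to 0.053). The list of 11, which includes the delivered Epas1, shifted up against all other genes (camera, adjusted p = 0.049, against adjusted p = 0.32 with an estimated correlation). The 10 members other than Epas1 did not shift by camera (median 0.14, adjusted p = 0.28, fry 0.036), and the list of 11 did not pass without Ad-Epas1 replicate 1 (0.059), Ad-Epas1 replicate 2 (0.083), Ad-Epas1 replicate 3 (0.060) or Mock replicate 2 (0.065).

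The 10 largest rises among genes with settled names were those of Epas1, Cxcl3 (4.47), Depp1 (4.44), Car12 (4.37), Egln3 (4.05), Prok2 (3.92), Pgf (3.86), Nos2 (3.66), Slc7a11 (3.48) and Esm1 (3.40), all as log2 fold changes. Car12 is a membrane carbonic anhydrase and rose 20.7-fold (SE 0.13, adjusted p = 5.0e-05). Prok2 and Pgf encode secreted factors that act on blood vessels, and Nos2 encodes inducible nitric oxide synthase. The 10 largest falls were those of Hpgd (-4.84), Rspo2 (-4.01), Ccna2 (-3.44), Anln (-3.32), Cdo1 (-3.22), Aldh1a1 (-3.20), Klhdc8a (-3.08), H1f5 (-3.06), Lpl (-3.06) and Kif11 (-2.97). Hpgd, the enzyme that starts the breakdown of prostaglandins, was lower in Ad-Epas1 (SE 0.22 on the log2 scale, adjusted p = 3.1e-04). Rspo2, a secreted enhancer of Wnt signalling, was 16.1-fold lower (SE 0.25, adjusted p = 6.2e-04). In the Ad-Epas1 arrays Hpgd stood at 5.98, H1f5 at 4.72 and Kif11 at 6.22, and in Mock Cxcl3 stood at 5.88, Prok2 at 6.47 and Pgf at 5.27. For scale, 95% of 1394 olfactory and vomeronasal receptor genes lay below 6.62, so the fold changes of these 6 genes and their order are not exact. Of these 20 genes, Cxcl3, Pgf, Nos2, Slc7a11 and Lpl lost their call when 1 array was left out. Pgf and Lpl did so without any array but Ad-Epas1 replicate 3 (adjusted p up to 0.082 and 0.14), Cxcl3 and Slc7a11 without Mock replicate 2, Mock replicate 3, Ad-Epas1 replicate 1 or Ad-Epas1 replicate 2 (up to 0.12 and 0.10), and Nos2 without Mock replicate 2, Mock replicate 3 or Ad-Epas1 replicate 2 (up to 0.056). Without Ad-Epas1 replicate 3, the array with low macrophage transcripts, Lpl was at -2.02, Pgf at 4.86, Slc7a11 at 4.41 and Cxcl3 at 5.41. Other single arrays moved Cxcl3 (5.36 without Mock replicate 1, 3.75 without Ad-Epas1 replicate 1), Pgf (3.26 without Ad-Epas1 replicate 1), Nos2 (4.47 without Mock replicate 1) and Lpl (-3.69 without Ad-Epas1 replicate 2) by over 1.5-fold.

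Many genes known to respond to low oxygen rose. Of 38 measured hypoxia-responsive genes outside glycolysis, 16 rose, 2 fell and 20 did not pass (19 rose and 2 fell adjusted over the list alone). Their median log2 fold change was 0.50 (camera, adjusted p = 9.2e-07, against adjusted p = 0.33 with an estimated correlation). On Mock replicates 1, 2 and 3 the list's median lay at 0.15, -0.08 and -0.09 from the Mock mean. Egln3 stood at 9.15, 7.75 and 7.78 on these arrays. Beside Car12 and Egln3, Ndrg1, a stress-induced gene, rose by 1.42 (SE 0.10, adjusted p = 7.8e-04), and Adm, which encodes the vasodilator peptide adrenomedullin, rose by 1.26 (SE 0.09, adjusted p = 9.3e-04). Vegfa, the principal blood vessel growth factor, rose 3.19-fold (adjusted p = 0.0039). The fallen members were Ccnd1 (-2.19), which encodes cyclin D1, and Cybrd1 (-2.06), an iron reductase. Vegfa, Ccnd1 and Cybrd1 were chosen for naming after their values were seen.

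Some genes of glycolysis and glucose uptake rose. Among 19 measured genes, 6 rose, none fell and 13 did not pass (8 rose and 1 fell adjusted over the list alone). Pfkm (-0.49) and Eno2 (-0.28), named after their values were seen, fell without Ad-Epas1 replicate 3. Pfkp, a phosphofructokinase, rose by 1.05 (SE 0.11, adjusted p = 0.0026), the glucose transporter gene Slc2a1 by 0.66 (SE 0.12, adjusted p = 0.015) and the hexokinase gene Hk1 by 0.63 (SE 0.11, adjusted p = 0.013). Without Mock replicate 2, Mock replicate 3 or Ad-Epas1 replicate 2, the calls of Slc2a1 and Hk1 ended (adjusted p up to 0.070 and 0.065). The list shifted up with a median of 0.19 (camera, adjusted p = 0.014, against adjusted p = 0.52 with an estimated correlation, and 0.054 with the preset value but without Ad-Epas1 replicate 2). On Mock replicates 1, 2 and 3 its median lay at 0.12, -0.07 and -0.06 from the Mock mean. On Ad-Epas1 replicates 1, 2 and 3 it lay at 0.21, 0.28 and 0.13, so Mock replicate 1 was close to Ad-Epas1 replicate 3. In oxidative phosphorylation, 1 of 29 measured genes rose and 1 fell, with the same counts adjusted over the list alone. These were the complex I subunit genes Ndufa1 (0.32, adjusted p = 0.025) and Ndufa2 (-0.29, adjusted p = 0.021), each of which lost its call without any of several arrays (adjusted p up to 0.11 and 0.090). Ndufs1 differed by -0.24 (adjusted p = 0.059), and 2 members fell without Ad-Epas1 replicate 3, Ndufa2 and Ndufv1, the latter named after its value was seen. The median of the list was -0.14 (camera, adjusted p = 0.0040, against adjusted p = 0.30 with an estimated correlation).

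**Figure D2:**
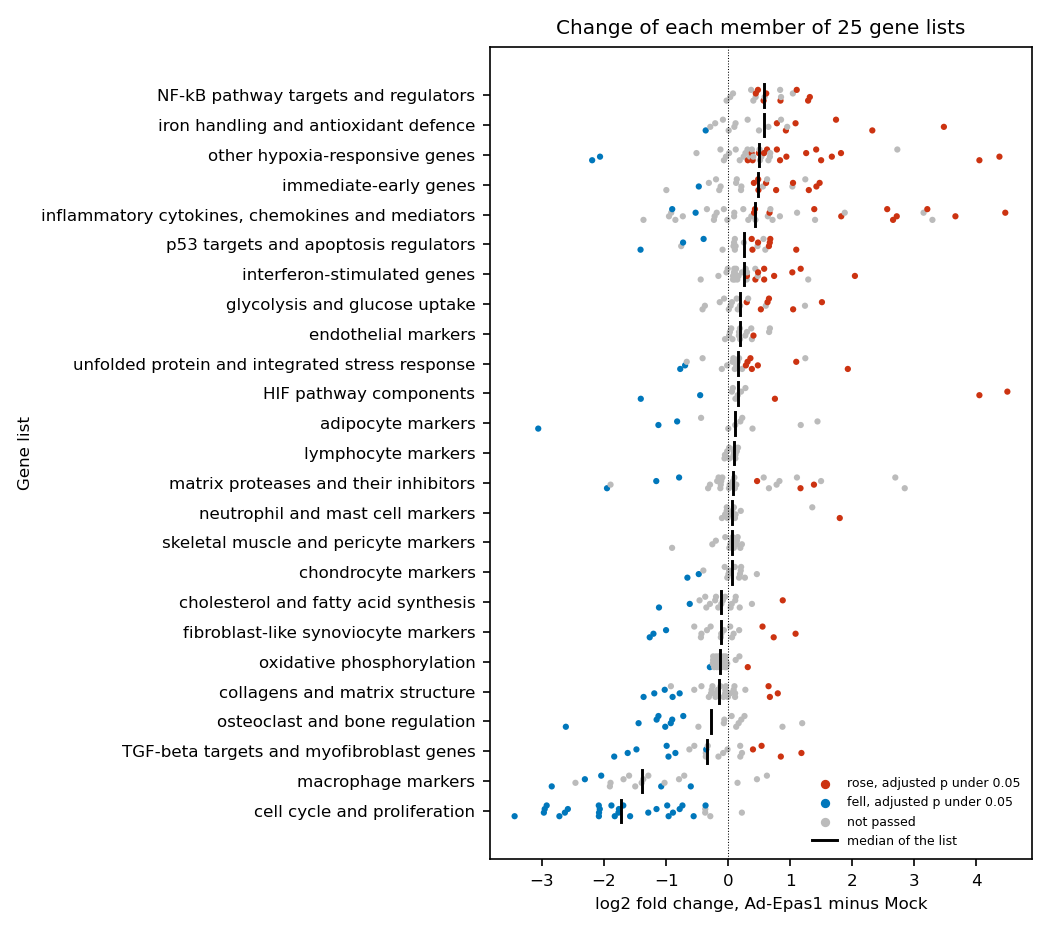
Log2 fold change (Ad-Epas1 minus Mock, horizontal axis) of every measured member of the 25 tested gene lists (vertical axis, ordered by median). Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and black bars mark each list's median, from -1.72 for the cell cycle list to 0.58 for the NF-kB list.

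Some inflammatory mediators rose in Ad-Epas1 cells. Of 39 measured cytokines, chemokines and mediators, 11 rose, 2 fell and 26 did not pass (12 rose and 3 fell adjusted over the list alone). Ptgs2, which encodes cyclooxygenase-2, rose 6.31-fold (log2 fold change 2.66, SE 0.11, adjusted p = 3.1e-04). The cytokine gene Lif rose by 2.56 (SE 0.19, adjusted p = 9.8e-04), Il6 by 2.72 (SE 0.64, adjusted p = 0.032) and the neutrophil-attracting chemokine gene Cxcl1 by 1.82 (SE 0.34, adjusted p = 0.016). Csf1, the macrophage growth factor, fell by 0.90 and Il18 fell by 0.52. Nampt, a NAD-producing enzyme also found outside cells, differed by -0.23 (adjusted p = 0.078). Within Mock, replicate 1 was higher than replicates 2 and 3 for several of these genes: Il6 stood at 10.4 there against 7.96 and 8.10, and Nos2 at 10.7 against 8.35 and 8.24. The interleukin-1 genes did not pass over all arrays. Il1b stood at 12.7 and 12.2 in Ad-Epas1 replicates 1 and 2, at 5.54 in Ad-Epas1 replicate 3, and at 8.57, 6.06 and 6.34 in Mock replicates 1, 2 and 3 (adjusted p = 0.29, and 0.0028 without Ad-Epas1 replicate 3). That array, which also held low macrophage transcripts (described with the cell type markers), decided the count of this list: 21 members rose and 3 fell without it. The list shifted up with a median of 0.43 (camera, adjusted p = 0.014, against adjusted p = 0.52 with an estimated correlation, and 0.083 with the preset value but without Ad-Epas1 replicate 2). On Mock replicates 1, 2 and 3 its median lay at 0.22, -0.12 and -0.13 from the Mock mean. On Ad-Epas1 replicates 1, 2 and 3 it lay at 0.39, 0.58 and 0.15, so Mock replicate 1 was above Ad-Epas1 replicate 3. Without Mock replicate 1 the rise of Il6 was 3.52. Il6 and Cxcl1 lost their calls without Mock replicate 2, Mock replicate 3, Ad-Epas1 replicate 1 or Ad-Epas1 replicate 2 (adjusted p up to 0.12 and 0.071). Csf1, Il18 and Il1b were chosen for naming after their values were seen.

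Targets and regulators of NF-kB, a transcription factor family of inflammation, moved in 1 direction among called genes. Of 18 measured members, 8 rose, none fell and 10 did not pass (11 rose and none fell adjusted over the list alone), with a median of 0.58 (camera, adjusted p = 6.2e-05, against adjusted p = 0.49 with an estimated correlation). On Mock replicates 1, 2 and 3 the list's median lay at 0.33, -0.20 and -0.15 from the Mock mean. On Ad-Epas1 replicates 1, 2 and 3 it lay at 0.73, 0.63 and 0.42. Nfkbiz, an inducible member of the inhibitor family, rose by 1.32 (SE 0.15, adjusted p = 0.0038), Zc3h12a, a ribonuclease that degrades cytokine transcripts, by 1.29 (SE 0.15, adjusted p = 0.0036) and Cflar, an inhibitor of caspase-8, by 0.48 (SE 0.06, adjusted p = 0.0047). Among interferon-stimulated genes, 9 of 30 rose, none fell and 21 did not pass (10 rose and none fell adjusted over the list alone), with a median of 0.25 (camera, adjusted p = 6.9e-04, against adjusted p = 0.30 with an estimated correlation). The antiviral gene Rsad2 rose 4.12-fold (adjusted p = 0.0060). Stat2, a transducer of interferon signals, rose by 0.48 (adjusted p = 0.0048), and Zbp1, a sensor of viral nucleic acid, by 0.58 (adjusted p = 0.0059). Ifit2, named after its value was seen, fell by 0.77 without Ad-Epas1 replicate 3. Both groups had received an adenovirus. Of 23 measured immediate-early genes, 9 rose, 1 fell and 13 did not pass (11 rose and 1 fell adjusted over the list alone), with a median of 0.48 (camera, adjusted p = 0.0041, against adjusted p = 0.30 with an estimated correlation). The examples were Ier3 (1.47, adjusted p = 0.0028), Maff (1.05, adjusted p = 9.3e-04) and Junb (0.77, adjusted p = 0.0040), and the fallen member was Myc (-0.47), named after its value was seen.

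Most transcripts of cell division fell. Of 30 measured cell cycle genes, 26 fell, none rose and 4 did not pass (29 fell and none rose adjusted over the list alone). The median was -1.72 (camera, adjusted p = 4.6e-23, against adjusted p = 0.30 with an estimated correlation). Ccnb2, a mitotic cyclin, was 7.76-fold lower (log2 fold change -2.96, SE 0.14, adjusted p = 3.1e-04), Mcm5, a subunit of the replicative helicase, 2.99-fold lower (SE 0.08, adjusted p = 4.0e-04) and Tk1, thymidine kinase, 2.44-fold lower (SE 0.08, adjusted p = 5.3e-04). On each Ad-Epas1 array the list's median lay between -1.77 and -1.54 from the Mock mean. On Mock replicates 1, 2 and 3 it lay at -0.29, 0.17 and 0.16. Of 21 measured p53 targets and apoptosis regulators, 7 rose, 3 fell and 11 did not pass (10 rose and 3 fell adjusted over the list alone). Mdm2, which encodes the ubiquitin ligase of p53, rose by 0.66 (adjusted p = 0.0045). The sestrin genes moved apart, Sesn2 rising by 1.10 (adjusted p = 0.0015) and Sesn1 at -1.41 (adjusted p = 0.0017). The list's upward shift (camera, adjusted p = 0.041, against adjusted p = 0.30 with an estimated correlation) did not pass without Mock replicate 1 (0.083), Ad-Epas1 replicate 2 (0.051) or Ad-Epas1 replicate 3 (0.057).

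Stress responses and antioxidant genes rose in part. Of 21 measured genes of the unfolded protein and integrated stress responses, 7 rose, 2 fell and 12 did not pass (7 rose and 3 fell adjusted over the list alone). Ppp1r15a, which restores translation after stress, rose by 1.93 (SE 0.15, adjusted p = 0.0011), and Asns, asparagine synthetase, fell by 0.69 (SE 0.10, adjusted p = 0.0069). The list's shift (camera, adjusted p = 0.049, against adjusted p = 0.49 with an estimated correlation) did not pass without Mock replicate 1 (0.18), Ad-Epas1 replicate 1 (0.055) or Ad-Epas1 replicate 2 (0.092). With Epas1 left out of the lists it did not pass either (0.0502). Epas1 is not a member of this list, so that value moved only through the other genes and the adjustment over lists. Of 18 measured genes of iron handling and antioxidant defence, 6 rose, 1 fell and 11 did not pass (9 rose and 2 fell adjusted over the list alone), with a median of 0.57 (camera, adjusted p = 0.014, against adjusted p = 0.52 with an estimated correlation). In the fit without Ad-Epas1 replicate 3, the macrophage-poor array, 10 rose and 1 fell. The quinone reductase gene Nqo1 rose 5.01-fold (adjusted p = 0.0014), Gclc, which catalyses the first step of glutathione synthesis, 3.34-fold (adjusted p = 0.0037) and Srxn1, sulfiredoxin, 2.12-fold (adjusted p = 0.016). Srxn1 lost its call without Mock replicate 2, Mock replicate 3, Ad-Epas1 replicate 1 or Ad-Epas1 replicate 2 (adjusted p up to 0.073). In cholesterol and fatty acid synthesis, 1 of 19 measured genes rose and 2 fell, with the same counts adjusted over the list alone, and the list did not shift (camera, adjusted p = 0.27). Sqle, squalene epoxidase, rose by 0.88 (adjusted p = 0.0097). The fatty acid synthesis genes Elovl6 (-1.11, adjusted p = 0.019) and Acaca (-0.62, adjusted p = 0.046) fell. Single arrays ended these calls, with adjusted p up to 0.051 for Sqle without Mock replicate 2, 0.080 for Elovl6 without Mock replicate 3 and 0.14 for Acaca without Mock replicate 2. Without Ad-Epas1 replicate 3, the macrophage-poor array, this list passed, downward (camera, adjusted p = 0.0025, 6 members fallen and 1 risen).

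Matrix-degrading enzymes, a central concern in arthritis, went both ways. Of 29 measured proteases and inhibitors, 3 rose, 3 fell and 23 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.71). Ctsk, the collagen-degrading cathepsin K, rose by 1.38 (SE 0.11, adjusted p = 0.0012), and Mmp3, stromelysin-1, rose by 0.47 from an already high level of 12.6 (SE 0.08, adjusted p = 0.014). Timp3, an inhibitor of matrix proteases, was 3.87-fold lower (adjusted p = 0.0062), and the protease gene Adamts12 was 1.73-fold lower (adjusted p = 0.0018). The gelatinase gene Mmp9 (2.82-fold, adjusted p = 0.069), the collagenase gene Mmp13 (1.77-fold, adjusted p = 0.17) and the aggrecanase gene Adamts4 (1.72-fold, adjusted p = 0.12) did not pass. Ad-Epas1 replicate 3, the array with low macrophage transcripts, decided this: without it 12 members rose and 5 fell, the list passed upward (adjusted p = 0.035), and Mmp9 (log2 fold change 2.04, adjusted p = 0.0012), Adamts4 (1.09, adjusted p = 0.0079) and Mmp13 (1.13, adjusted p = 0.044) passed. On that array Ctss, also in the macrophage list, stood at 5.57 against 11.4 to 11.6 on the other 5, Mmp8 at 6.24 against 11.6 and 10.7 in Ad-Epas1 replicates 1 and 2, and Mmp12 at 9.12 against 11.15 and 10.97, all named after their values were seen. Mmp3 lost its call without Mock replicate 2, Mock replicate 3 or Ad-Epas1 replicate 2 (adjusted p up to 0.070).

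Among 30 measured collagens and matrix structure genes, 3 rose, 5 fell and 22 did not pass (4 rose and 10 fell adjusted over the list alone), and 12 fell without Ad-Epas1 replicate 3, the macrophage-poor array. Col6a3, a collagen VI chain, rose by 0.65 (adjusted p = 0.0046) and the hyaluronan synthase gene Has1 by 0.80 (adjusted p = 0.0097). Col8a1, a short-chain collagen, fell by 0.78 (adjusted p = 0.012). Leaving out Mock replicate 3 ended the call of Has1 (adjusted p = 0.052), and leaving out Mock replicate 2, Mock replicate 3 or Ad-Epas1 replicate 2 that of Col8a1 (up to 0.060). The list's downward shift (camera, adjusted p = 0.028, against adjusted p = 0.52 with an estimated correlation) did not pass without Ad-Epas1 replicate 1 (0.069). Of 22 measured TGF-beta targets and myofibroblast genes, 4 rose, 7 fell and 11 did not pass, with the same counts adjusted over the list alone. Id3 (-1.84, adjusted p = 0.0041) and Id1 (-1.62, adjusted p = 0.0054), which encode inhibitors of DNA binding that respond to BMP signals, fell, as did Tagln, a smooth muscle cytoskeletal gene (-1.48, adjusted p = 0.0048). That list shifted down (camera, adjusted p = 0.035, against adjusted p = 0.49 with an estimated correlation), and did not pass without Mock replicate 3 (0.091) or Ad-Epas1 replicate 3 (0.095). Its median lay at -0.21, 0.05 and 0.12 from the Mock mean on Mock replicates 1, 2 and 3. On Ad-Epas1 replicates 1, 2 and 3 it lay at -0.14, -0.29 and -0.19, so Mock replicate 1 was within the Ad-Epas1 range.

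Several bone-regulating genes fell. Of 18 measured regulators of osteoclasts and bone, 8 fell, none rose and 10 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.012, against adjusted p = 0.30 with an estimated correlation). Bmp4, a bone morphogenetic protein, was 6.13-fold lower (log2 fold change -2.62, SE 0.07, adjusted p = 2.5e-05). The secreted Wnt modulators Dkk3 (-1.15, adjusted p = 0.0072) and Sfrp2 (-0.72, adjusted p = 0.0075) fell. A dimmer probe set of Sfrp2 did not change (-0.04, limma over probe sets, adjusted p = 0.86). Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor for RANKL, was 2.02-fold lower (SE 0.19, adjusted p = 0.016). Tnfsf11, which encodes RANKL itself, differed by -0.48 with a 95% interval from -1.20 to 0.24 (adjusted p = 0.31). Bmp2, named after its value was seen, rose by 1.35 without Ad-Epas1 replicate 3 (adjusted p = 0.0033). Tnfrsf11b lost its call without Mock replicate 2 or Mock replicate 3 (adjusted p up to 0.072). Csf1 and Tnfrsf11a, a growth factor and a receptor of osteoclast precursors and macrophages, were also among the fallen members. On Ad-Epas1 replicate 3, the array with low macrophage transcripts, Tnfrsf11a stood at 7.21, against 8.17 and 8.12 in Ad-Epas1 replicates 1 and 2 and at least 8.80 in Mock, and it was named after its values were seen.

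Markers of the synovial fibroblasts themselves went both ways. Of 18 measured, 3 rose, 3 fell and 12 did not pass (3 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.098). Pdpn, podoplanin, rose by 0.73 (adjusted p = 0.0041), while the growth factor receptor gene Pdgfrb (-1.20, adjusted p = 0.0044) and Cdh11, the adhesion molecule of synovial fibroblasts (-1.26, adjusted p = 0.011), fell. Cdh11 lost its call without Mock replicate 2 or Mock replicate 3 (adjusted p up to 0.056). Without Ad-Epas1 replicate 3, the macrophage-poor array, the list passed, downward (adjusted p = 0.034, 6 members fallen).

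Macrophage transcripts set Ad-Epas1 replicate 3 apart from the other arrays. The labels describe cultures with over 90% CD90-positive and under 1% CD14-positive cells by flow cytometry. On 5 of the 6 arrays macrophage genes were nonetheless high: Lyz2, the macrophage lysozyme, stood between 12.8 and 12.9 on those arrays and at 7.15 on Ad-Epas1 replicate 3, and Adgre1, a macrophage surface receptor, between 11.7 and 12.7 and at 5.89. The median of the 20 markers was 0.01 from the Mock mean in Ad-Epas1 replicate 1, -0.08 in replicate 2 and -3.80 in replicate 3. Over all arrays 5 markers fell, none rose and 15 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.0034, against adjusted p = 0.52 with an estimated correlation). Without Ad-Epas1 replicate 3, 3 rose and 6 fell, and the list did not pass (adjusted p = 0.17). The chemokine receptor gene Cx3cr1 (-1.08, adjusted p = 0.0022), the complement gene C1qa (-2.05, adjusted p = 0.0089) and the mannose receptor gene Mrc1 (-2.84, adjusted p = 0.0094) fell, and these 3 passed without Ad-Epas1 replicate 3 too. Cd14, in contrast, stood at 11.9 and 11.4 in Ad-Epas1 replicates 1 and 2 against 9.99 to 10.4 in Mock, and at 8.62 in replicate 3 (adjusted p = 0.72, and 0.0025 without it). Xist, the X-inactivation transcript of female cells, stood at 10.4 on Ad-Epas1 replicate 3 and between 5.49 and 5.88 on the other arrays. None of the 4 measured sex-linked genes passed in limma, adjusted over the list alone included, with 1 at an unadjusted p under 0.05 and 0 by the per-gene test without shared variance. Of the Y-linked genes, Eif2s3y lay between 9.11 and 9.37 and Kdm5d between 8.42 and 9.01 over all arrays. Epas1 itself on this array was 4.48 above the Mock mean. Lyz2, Adgre1 and Cd14 were chosen for naming after their values were seen.

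**Figure D3:**
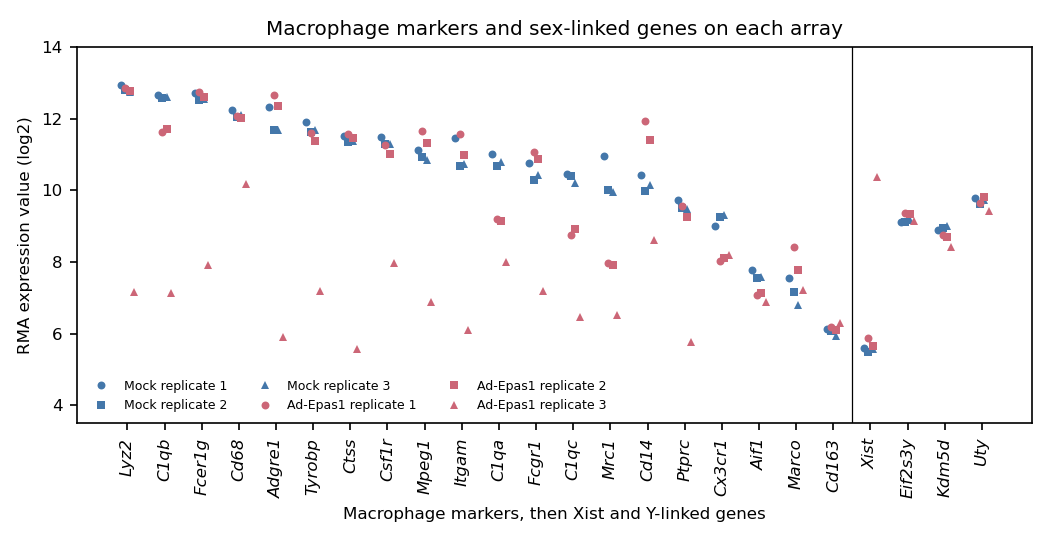
RMA expression values (log2, vertical axis) of the 20 macrophage markers, ordered by Mock mean, and of Xist and 3 Y-linked genes (horizontal axis) on each of the 6 arrays, with blue for Mock, red for Ad-Epas1 and symbols for the replicate numbers. Ad-Epas1 replicate 3 stands apart, with Lyz2 at 7.15 where the other arrays lie between 12.8 and 12.9, and Xist at 10.4 where they lie between 5.49 and 5.88.

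Other cell types of the joint gave low or mixed signals. Of 16 measured endothelial markers, 1 rose, none fell and 15 did not pass (4 rose and none fell adjusted over the list alone). This was Egfl7 (0.41, adjusted p = 0.038), which lost its call without any array but Ad-Epas1 replicate 3 (adjusted p up to 0.14). Tek and Vwf differed by 0.67 (adjusted p = 0.054) and 0.28 (adjusted p = 0.059). Without Ad-Epas1 replicate 3, the macrophage-poor array, 7 members rose and none fell, and Tek (0.89, adjusted p = 9.7e-04) and Vwf (0.32, adjusted p = 0.030) passed. The endothelial list shifted up (camera, adjusted p = 0.022, against adjusted p = 0.49 with an estimated correlation), did not pass without Ad-Epas1 replicate 1 (0.059), and had a median Mock level of 6.52. Of 11 adipocyte markers, 3 fell, none rose and 8 did not pass (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.58). The fallen members were Lpl, lipoprotein lipase, and the transcription factor genes Pparg (-1.12, adjusted p = 0.0051) and Cebpa (-0.82, adjusted p = 0.0053), and the median of the list was 0.11 where its mean was -0.17. Fabp4 (1.42) and Cd36 (3.51), named after their values were seen, rose without Ad-Epas1 replicate 3, the macrophage-poor array, where Cd36 stood at 5.34 against 11.7 and 11.4 in Ad-Epas1 replicates 1 and 2. Of 14 chondrocyte markers, Hapln1 (-0.66, adjusted p = 0.018) and Col2a1 (-0.47, adjusted p = 0.049) fell, none rose and 12 did not pass (1 fell and none rose adjusted over the list alone). Their calls ended without single arrays (adjusted p up to 0.082 and 0.16), and the list did not shift (camera, adjusted p = 0.96, with a downward sign where the median was 0.06). Acan differed by 0.27 (adjusted p = 0.13). Among 13 neutrophil and mast cell markers 1 rose, none fell and 12 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.48). This was Camp, which encodes an antimicrobial peptide (1.80, SE 0.25, adjusted p = 0.0063). S100a8 (1.36, adjusted p = 0.23) and Mpo (0.20, adjusted p = 0.29) did not pass. S100a8 passed without Ad-Epas1 replicate 3 (2.14, adjusted p = 0.011) and stood at 0.60 without Ad-Epas1 replicate 1. None of 12 lymphocyte markers (camera, adjusted p = 0.52) or 14 skeletal muscle and pericyte markers (adjusted p = 0.70) passed in limma, adjusted over the list alone included. At an unadjusted p under 0.05 there were 0 and 1, and the per-gene test without shared variance passed 0 in both. Nearest to the threshold were Nkg7, a natural killer cell granule gene, at 0.12 (adjusted p = 0.25) and Cspg4 at -0.90 (adjusted p = 0.0501), which passed without Ad-Epas1 replicate 3 (-1.17, adjusted p = 0.0024).

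Over the 25 lists tested, 17 passed with the preset correlation of camera, 11 upward and 6 downward (15 with Epas1 left out, 9 upward and 6 downward), and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. The directional test of fry, which does not compare a list with other genes, passed 10 lists, 7 upward and 3 downward.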

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

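Probe sets without a gene in the platform annotation were outside the comparison of genes. Fitted with limma over all probe sets of the arrays, 637 of the 16010 changed between Ad-Epas1 and Mock at an adjusted p under 0.05, 381 of them higher and 256 lower in Ad-Epas1. What they measure was not analysed here, and no explanation was tested. In fits with 1 array left out, chosen after seeing the data, the count was 429 without Mock replicate 1, 272 without Ad-Epas1 replicate 1, 151 without Mock replicate 2, 227 without Ad-Epas1 replicate 2, 166 without Mock replicate 3 and 972 without Ad-Epas1 replicate 3.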

How the results depend on the processing

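Leaving out 1 array gave 1181 to 5390 changed genes (1181 without Mock replicate 3, 1187 without Mock replicate 2, 1512 without Ad-Epas1 replicate 2 and 2186 without Ad-Epas1 replicate 1), against 3620 with all. With a change of at least 1.5-fold it gave 954 to 2457 (954 without Mock replicate 2, 962 without Mock replicate 3 and 1092 without Ad-Epas1 replicate 2), against 1720. Each such fit has fewer arrays by construction. Without both Mock replicate 1 and Ad-Epas1 replicate 3, a setting chosen after seeing the data, 6000 and 2764 genes passed. Array weights gave 7791 genes, and the per-gene test without shared variance 1448 and 698. The cause of these moves was not tested. Between 12 and 16 lists passed when 1 array was left out, against 17. With Epas1 left out of the lists, chosen after seeing the data, 15 passed. Fry passed 10 lists, and camera with an estimated correlation 0. The remaining alternatives stayed within 1.5 times of these counts. No gene called by both fits changed sign under any of the 14 alternatives compared gene by gene. For fits that leave out or weight arrays this was fixed in advance, since the groups did not overlap for any called gene. The replicate block left 3108 genes and 15 lists. Whether the numbers pair the samples was not settled for numbers 1 and 2. For number 3, Xist stood at 5.58 in Mock and at 10.4 in Ad-Epas1. The macrophage marker median on these arrays lay at -0.06 and -3.80 from the Mock mean. These values argue against 1 shared culture for number 3, though not against a shared day. The deviations of same-numbered arrays correlated at 0.34, -0.19 and 0.21 across genes, and not every array correlated best with its own number. Deviations of 3 arrays from their own group mean depend on each other and cannot show that pairing is absent. Of the 17 lists, 6 passed under every alternative but the estimated correlation: other hypoxia-responsive genes, NF-kB, bone regulation, interferon-stimulated genes, cell cycle and immediate-early genes. Lists without a call turned in sign of their test. Matrix proteases did so without Ad-Epas1 replicate 2, where the median of the list was 0.0356 (0.0356 to 0.11 over single arrays left out, and 0.14 without both arrays). Chondrocyte markers did so without Ad-Epas1 replicate 1 (0.09) or Mock replicate 2 (0.06) and in fry (0.0620), and their median lay between -0.06 and 0.12 over single arrays left out and at -0.0747 without both arrays. The cause was not tested. Of 83 called named genes, 58 passed in every fit without 1 array, and 74 under every other alternative that tested them. Dim genes limit the fold changes, since levels under about 6.62 are shared with genes not expected in these cells.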

Other observations

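The gene groups in this and the next paragraph were all chosen after the data were seen, as were the tests in the later paragraphs except the host gene test of microRNA genes and the splits of the arrays. These groups hold genes that prompted them, so no p-value of a list is given for them. Of 19 kinetochore and spindle genes 19 fell, with a median of -1.87, among them Ect2 (-2.95), Ndc80 and Nuf2, the last 2 to levels of 6.42 and 6.39 in Ad-Epas1. Of 25 clustered histone genes 12 fell and none rose (median -0.52). In Ad-Epas1 the fallen histone genes H1f5 (4.72), H2bc12 (6.03), H2ac15 (4.20), H2ac21, H2bc18, H2ac20, H4c17 and H2bc9 stood under 6.62. Genes not expected in these cells reach that level. H2ac20, H4c17 and H2bc9 were under 6.62 in Mock too. Of the spindle genes, Ndc80, Nuf2, Kif15, Kif2c, Kif4, Kif18a, Ttk and Cenpk were under it in Ad-Epas1. The fold changes of all these genes are not exact, nor is the spindle median of -1.87, which is the value of Kif2c. Of 22 Wnt and R-spondin pathway genes 4 rose and 5 fell, and 8 fell without Ad-Epas1 replicate 3. Lgr5, a receptor of R-spondins (-2.89), Wnt16 (-2.06), Fzd8 (-1.83) and Fzd4 (-0.56) fell with Rspo2. The risen genes were Wnt11 (0.96), Wnt10b (0.64, from 6.45 in Mock), Wnt9a (0.61) and Axin2 (0.47).

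Of 13 angiogenic ligands 6 rose and 1 fell, and 2 fell without Ad-Epas1 replicate 3. Vegfa, Prok2, Pgf and Esm1, which prompted the group, are 4 of the 6, and the others were Apln (2.43) and Prok1 (0.41). Angpt1 fell between levels that were both under 6.62. Of 8 ligands of the EGF receptor family 3 rose, Ereg (2.54), Hbegf (2.16) and Epgn, which stood at 6.07 in Mock, and Nrg1 fell by 1.38. In prostaglandin metabolism 2 of 14 genes rose and 2 fell, and 4 rose without Ad-Epas1 replicate 3. Ptges, which makes prostaglandin E2, rose by 1.39 (adjusted p = 0.0498) with Ptgs2, while Hpgd and the receptor gene Ptger4 (-0.78) fell.

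The median of the macrophage markers was low on Ad-Epas1 replicate 3 (-3.80 from the Mock mean) and near the Mock mean on the other Ad-Epas1 arrays, while Mrc1, C1qa and Cx3cr1 lay below every Mock array on all 3. On replicate 3, 49 genes, 8 of them macrophage markers, lay over 16-fold below both other Ad-Epas1 arrays and 1, Xist, lay over 16-fold above. Removal of macrophages by Epas1 would lower the median on the other Ad-Epas1 arrays too, but the lower of the marker medians there was -0.0841. A mislabelled Mock sample would lack Epas1, which lay 4.48 above the Mock mean. Xist lay 4.48 above the highest other array, so a cell preparation that included female cells may account for the difference, and this remains a hypothesis.

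Inflammatory genes were higher on Ad-Epas1 replicates 1 and 2 than in Mock, 21 of them in the fit without Ad-Epas1 replicate 3. A larger macrophage share on those arrays would raise the macrophage markers, but the higher of the 2 marker medians was 0.0144. Single markers moved both ways in that fit, with Cd14 rising by 1.48 and Mrc1 at -2.36. A response of the macrophages present could supply the rise. If it supplied all of it, none of the 21 should lie above every Mock array on the macrophage-poor array. There 13 of the 21, including Ptgs2, Lif, Nos2, Il6 and Cxcl1, lay above every Mock array, and 8, including Il1a, Il1b and Ccl3, did not. Of the 8, Ccl20 (0.61) and Cxcl10 (0.25) lay above the Mock mean and the others below it. Of all 956 genes risen at least 1.5-fold without that array, 735 (76.9%) lay above every Mock array on it. The 21 were called with no minimum fold, so this share and theirs are at unlike thresholds. The macrophage-poor array is 1 array, which also stands apart by Xist, so it cannot separate a fibroblast from a macrophage source.

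MicroRNA genes inside Sfmbt2, placed there by the GRCm38.p6 gene table, rose together. Of 22 measured, 19 rose and none fell (median 1.28, from 0.003 to 3.09), and Sfmbt2 rose by 2.31 (SE 0.10, limma, adjusted p = 3.1e-04). Of all 472 measured microRNA genes, those inside Sfmbt2 included, 40 rose and 22 fell. If probes for microRNA genes follow the host transcript, others should do so too: outside Sfmbt2, 42 of 49 microRNA genes (85.7%, 95% interval 72.8 to 94.1) in 43 called host genes had the sign of the host, as had 15 of the 15 called. Cross-hybridisation within the microRNA families is a candidate explanation that 2 family members outside Sfmbt2 (median -0.14) are too few to weigh. The values may therefore reflect the host transcript, not mature microRNAs, which were not analysed here.

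The 6 arrays can be split 10 ways into groups of 3, too few for a share under 0.05. The real split gave 3620 genes, 1720 genes changed at least 1.5-fold and 17 lists, and it was the 1 split of 10 with as many in each case (1, 1 and 1). The highest other split gave 1 gene, 1 gene at 1.5-fold and 14 lists.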
